A study of Homo sapiens with 26 samples.

How the data were processed

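RNA was measured in 26 samples of U-2 OS cells in 10 groups. In 4 preparations, stress granule cores were isolated by differential centrifugation and pulldown, and each was paired with a total RNA group taken from cytoplasm without nuclei. According to the labels, libraries were made after depletion of ribosomal RNA. The labels name FastQC, Trimmomatic 0.32, TopHat2 2.0.6 with Bowtie2 2.0.2, and Cuffdiff 2.2.1 as the authors' tools. The values are FPKM in the authors' deposited table, which gives 1 value for each group, so values of single samples were not used here and the depth per sample is unknown. For each of 4 comparisons the authors' deposited table also gives a fold (ratio of core FPKM over total FPKM), a test statistic, a p-value, a q-value, a yes or no flag and a class. The smallest deposited p-value is 5e-05 and was shared by 4006, 3158, 1553 and 3458 genes, so ranks among them carry no information.

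All 12657 genes of the table were used, and 12383 of them have values in the GFP-G3BP comparison. Of the group columns, 2 that match no sample in the labels were not used, and 6 samples in 2 groups without a column were not used either. Comparisons with unstressed cells and the relation to transcript length were planned and not run, since the table as used here holds neither. Where a symbol stands in several rows (65 rows of 29 symbols), the row with the highest mean total FPKM was taken. A locus is shared with another gene of the table for 4849 genes, so that reads of overlapping genes are not told apart by position. Start positions are printed as counted from 1.

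The log2 ratio is that of the deposited fold, which equals the ratio of the deposited group FPKM values within 6.64e-06. A pseudocount of 1 had been planned, and after the table was seen the deposited ratio was taken in its place, because the deposited classes rest on it. A gene was called where the deposited q-value was under 0.05 and the fold at least 2 in either direction. Genes with a core value of 0 (105, 90, 65 and 51) have no ratio and were never called. The classes were worked out anew from each comparison's own q-values, since the flag of the parental sorbitol comparison repeats that of arsenite. Because groups have 1 value each, no model was fitted across samples.

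Differences between 2 preparations were described as differences of log2 ratios. After the table was seen a test was added. Its standard error for each ratio is the log2 ratio over the size of the deposited statistic times a factor fitted so that the statistic gives the deposited p-value (1.78, 1.46, 1.81 and 1.77, from genes with p between 0.001 and 0.9). The two-sided p-values come from the normal distribution and were adjusted by Benjamini-Hochberg over all genes of a pair. The factor was carried beyond the p-values it was fitted on. Very small q-values of this test thus rest on the assumed normal tail, and their size is not precise. No minimum fold was set for this test, though at least 2-fold had been planned for calls on differences. A stricter form uses the deposited statistic as it stands. The test was tested on simulated data with 200 changed genes per run and noise drawn at the assumed error, in which at most 10 unchanged genes were called. Of 200 genes set 1 apart on the log2 scale it found 24 for ΔΔG3BP1/2 against parental, 107 for GFP against PABPC1 and 92 for arsenite against sorbitol, and of 200 set 2 apart 138, 177 and 161, so the numbers of genes found in these pairs do not compare like with like. This does not show whether the assumed error fits the real values. Total RNA groups of different comparisons were normalised separately by the authors and their differences were not tested.

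Before the data were examined, 25 gene lists, the comparisons and a rule for named genes were set. The rule takes the 5 strongest enriched and 5 strongest depleted genes of each comparison with FPKM of at least 5 in the higher group and symbols other than those of small nucleolar RNAs, microRNAs and unnamed loci, LINC or antisense genes, the 2 members of each list with the most FPKM in totals, the genes farthest apart between preparations, stress genes with the largest changes in totals, and a fixed set of reference genes. Some genes that the rule takes are not reported here. Each list's median was set against 10000 random lists of equal size, matched in 20 bins of expression. In simulated lists, 4 of 60 without a shift lay outside the central 95% of random lists, and 60 of 60 shifted by 1 lay above it. Lists of symbols used current names, and older names that belong to 1 gene only.

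Alternatives were pseudocounts of 0.1, 1 and 5, FPKM of at least 5 or 10, a q-value under 0.01, no minimum fold, a minimum of 0.58 on the log2 scale for shared calls, ratios centred on their median, equal upper quartiles, leaving out 242 mitochondrial and small noncoding RNA genes, the deposited classes, and Spearman's in place of Pearson's correlation. A correlation counted as moved beyond 0.05, a list median beyond 0.2, a share of calls beyond 5 percentage points and a count beyond 1.5 times. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.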

Results

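Stress granules are assemblies of untranslated mRNA and protein that form in the cytoplasm of stressed cells, and their stable cores can be spun down and pulled out of a lysate with an antibody. RNA from such cores was sequenced beside total cytoplasmic RNA of the same kind of U-2 OS cells, a human osteosarcoma line. The title and labels set the question of whether RNA enters the granules without G3BP1 and G3BP2, a pair of RNA-binding proteins on which granule assembly often depends. The series holds 26 samples in 10 groups. Parental cells gave 3 core and 3 total samples after 0.5 mM arsenite for 1 hour, and 2 core and 2 total samples after 0.5 M sorbitol for 2.5 hours. Cells labelled ΔΔG3BP1/2, in which both genes are disrupted according to the labels, gave 2 core and 2 total samples after sorbitol. Those 3 preparations used an antibody against the poly(A)-binding protein PABPC1. Cells carrying GFP-tagged G3BP gave 3 core samples, pulled down through GFP, and 3 total samples after sorbitol. The other 6 samples, totals of unstressed GFP-G3BP and ΔΔG3BP1/2 cells, have no column in the table and were not analysed here. The series holds no cores of unstressed cells and no mock pulldown. Entry into granules therefore cannot be told from what the spin and the bait recover.

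The authors' deposited table lists 12657 genes with 1 FPKM value per group rather than per sample, so no spread between replicates can be given here and the depth of the samples is unknown. Each gene's ratio is the FPKM in cores over the FPKM in total RNA of the same preparation, on the log2 scale. The median log2 ratio over all genes was -0.10, -0.01, -0.01 and -0.07 in the 4 preparations, so centring raises ratios by that much, and making upper quartiles equal raises them by 0.13, 0.10, 0.15 and 0.12. A gene was called enriched or depleted where q in the authors' deposited table was under 0.05 and the ratio was at least 2-fold up or down. Values for the 4 preparations are given throughout in the order parental arsenite, parental sorbitol, ΔΔG3BP1/2 sorbitol and GFP-G3BP sorbitol. The 4 comparisons were normalised separately by the authors, so levels set side by side across them are descriptive. Counts within gene lists use q over all genes, and adjusted over the list alone the count of enriched or depleted members differed in 16 of 100 pairings of list and preparation, by at most 3 members.

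G3BP1 mRNA (ENSG00000145907, chromosome 5, 151121877 to 151192346) stood at 568, 250.3, 190 and 1026 FPKM in total RNA. G3BP2 mRNA (ENSG00000138757, chromosome 4, 76567966 to 76649709) stood at 81.1, 98.3, 85.1 and 54.0 FPKM. Both mRNAs were thus present in the cells labelled ΔΔG3BP1/2, at 0.757 and 0.866 times the parental sorbitol level. An mRNA level does not measure the protein. In the cores, G3BP1 was called in none of the preparations, with log2 ratios of 0.02, -0.25, -0.06 and -0.29, and its sign in the ΔΔG3BP1/2 cells turns positive when the ratios are rescaled to equal upper quartiles. G3BP2 stood at -0.08, 0.70, 0.70 and 0.45, also without a call, and its arsenite value turns positive under either rescaling. The genome build behind these coordinates is not given in the sources used here.

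The first comparison asks which RNAs stand higher or lower in cores than in total RNA after arsenite, which binds thiols and blocks translation initiation. Arsenite cores held much more of the very long mRNAs than total RNA did. AHNAK (ENSG00000124942, chromosome 11, 62201016 to 62323707), which encodes a giant scaffold protein, stood at 1206 FPKM in cores and 194 FPKM in total RNA, a log2 ratio of 2.63. The histone methyltransferase gene KMT2D had a log2 ratio of 2.73 and the dynein heavy chain gene DYNC1H1 had 2.16. At the other end, the small RNAs of the signal recognition particle and of RNase P stood far lower in cores, RN7SL3 at -6.92 and RPPH1 at -6.39. Each of these 5 genes had a q of 0.000209 in the authors' deposited table, the smallest of that comparison.

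In arsenite cores 1189 genes were called enriched and 1775 depleted by the q values of the authors' deposited table. Of 45 measured mRNAs for giant cytoskeletal and other very large proteins, 40 were enriched and none was depleted, with a median log2 ratio of 1.65 and examples AHNAK2 at 2.71, the spectraplakin gene MACF1 at 2.27 and the non-muscle myosin gene MYH9 at 1.18. MACF1 was picked after its values were seen. Chromatin regulators with long mRNAs had 30 of 44 members enriched and a median of 1.47, with the remodeller CHD4 at 1.68. Among mRNAs of secreted and matrix proteins 17 of 37 were enriched and 1 was depleted, with COL1A1 at 1.52 and FN1 at 1.07, while SPARC and TGFBI stood at -0.35 and -0.86 without a call. COL1A1 and FN1 were picked after their values were seen. Of the 15 RNAs made inside mitochondria, 8 were enriched and none was depleted, with MT-CO2 at 0.39 and MT-CO3 at 0.04 not called. A list of mRNAs followed in granule imaging studies had 6 of 10 members enriched, with the kinase gene CDK6 at 1.38, while TFRC and CTNNB1 stood at 0.45 and 0.52 without a call.

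Several lists had most of their members on the depleted side in arsenite. Ribosomal protein mRNAs were depleted in 68 of 71 cases, with a median of -1.96 and RPL38 at -1.96. Nuclear mRNAs for oxidative phosphorylation were depleted in 53 of 69 cases, with UQCRQ of respiratory complex III at -2.06. Replication-dependent histone mRNAs, which carry no poly(A) tail, were depleted in 35 of 36 cases, with HIST1H3B at -3.93. Hosts of small nucleolar RNAs were depleted in 11 of 16 cases, with SNHG3 at -3.76. The remaining genes among the 5 strongest on each side were TNRC18 at 2.65 and RP11-2F9.3 at 2.97 among the enriched, and RN7SKP203, RNU4-1 and RNU2-6P at -5.65, -5.27 and -4.90 among the depleted. The uncalled genes in between numbered 9588, and 105 more had a core value of 0. With upper quartiles made equal, 1536 genes were enriched and 1437 depleted, and with ratios centred on their median 1441 and 1505, so the excess of depleted genes depends on the scaling.

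The second comparison asks the same of parental cells after sorbitol, which draws water out of the cell. Sorbitol cores also held more mRNA of chromatin regulators and less of the small structured RNAs. Among the strongest single genes ZMIZ1, a transcriptional co-activator, had a log2 ratio of 2.43 and the zinc finger factor CASZ1 had 2.34. RPPH1 was depleted at -10.45 and RMRP, the RNA of RNase MRP, at -6.84. The mRNA of PABPC1 itself (chromosome 8, 101698044 to 101735037), the protein that carried the pulldown, was enriched at 1.23. All of these had a q of 0.000268 in the authors' deposited table.

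Sorbitol cores of parental cells had 998 genes called enriched and 1716 depleted by the q values of the authors' deposited table. Equal upper quartiles gave 1317 and 1523. Chromatin regulators were enriched in 32 of 44 cases, with a median of 1.23. Giant-protein mRNAs were enriched in 13 of 45 cases and had a median of 0.83, with AHNAK at 1.10 and DYNC1H1 at 0.73. Genes for the granule's own proteins had 9 of 38 mRNAs enriched and none depleted, with a median of 0.62, while G3BP1 was not called. Ribosomal protein mRNAs were depleted in 68 of 71 cases with a median of -2.35, and RPL37A stood at -2.85. Oxidative phosphorylation mRNAs were depleted in 52 of 69 cases, with NDUFB9 at -2.43, and histone mRNAs in 30 of 36, with HIST1H1C at -3.04. Mitochondrially encoded RNAs had 1 enriched and 5 depleted members, MT-ND6 at 1.69 and MT-CO3 at -1.67 among them. The other strongest genes were AP000275.65 at 2.50, the G-protein subunit GNAO1 at 2.35 and NHSL1 at 2.34 on the enriched side, and RN7SL3, RN7SKP203 and RNU5B-1 at -8.32, -7.04 and -5.35 on the depleted side. The class column of the authors' deposited table lists 791 enriched and 1355 depleted genes for this comparison, fewer than its own q values give.

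The third comparison asks which RNAs stand higher or lower in cores than in total RNA in cells labelled ΔΔG3BP1/2 after sorbitol. ZC3H4, a zinc finger gene, led with a log2 ratio of 2.46, followed by the kinase gene HIPK2 at 2.25 and the mitochondrial MT-ND6 at 2.22. The noncoding RNA NORAD (LINC00657, ENSG00000260032, chromosome 20, 34633544 to 34638882), which binds Pumilio proteins, was enriched at 1.55. RPPH1 stood at -10.23 and RN7SL3 at -8.79. All of these had a q of 0.000555 in the authors' deposited table.

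Cores of the cells labelled ΔΔG3BP1/2 had 884 genes called enriched and 1380 depleted by the q values of the authors' deposited table. Chromatin regulators were enriched in 30 of 44 cases and giant-protein mRNAs in 19 of 45, with medians of 1.23 and 0.98 and with CHD4 at 1.19 and AHNAK at 1.77. Adjusted over the list alone, these counts were 33 and 21. Ribosomal protein mRNAs were depleted in 60 of 71 cases, oxidative phosphorylation mRNAs in 44 of 69 and histone mRNAs in 28 of 36. RPL37A stood at -2.43, UQCRQ at -2.47 and HIST1H3B at -3.81. The other strongest genes were RP11-598P20.3 and RP11-215G15.5 at 2.15 and 2.13, and RN7SKP203, RNU5B-1 and RMRP at -6.57, -6.36 and -6.24. With upper quartiles made equal, 1233 genes were enriched and 1171 depleted.

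Set against parental cells, the cells labelled ΔΔG3BP1/2 gave closely similar core ratios after sorbitol, with the same sign for 91.7% of genes. Both preparations used the PABPC1 antibody, so whatever that bait recovers is common to them. CDK6, at 0.91 against 1.13, NORAD, at 1.55 against 1.29, and GAPDH, at -1.28 against -1.14, stood close to their parental log2 ratios. Other reference genes stood farther apart, AHNAK at 1.77 against 1.10, DYNC1H1 at 1.26 against 0.73 and PABPC1 at 0.82 against 1.23. The log2 ratios correlated across 12552 genes with Pearson's r of 0.951 and Spearman's rho of 0.954, and the slope was 0.975. Genes are not independent replicates. Of the genes enriched in parental cells 680, or 68.1%, were also called in the ΔΔG3BP1/2 cells, against 69.7 if the calls were independent. Of the depleted genes 1249, or 72.8%, were shared, against 187 if independent. No gene was called in opposite directions. All of the 318 genes enriched in parental cells and not called in the ΔΔG3BP1/2 cells had a positive ratio there, with a median of 0.92.

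The difference between the cell types was tested with errors taken back from the authors' deposited statistics, a test added after the table was seen. It found 5 of 12418 genes, 1 higher and 4 lower in the ΔΔG3BP1/2 cells, and 4 of the 5 were also at least 2-fold apart. The higher gene was RPS27, a ribosomal protein gene (chromosome 1, 153963235 to 153964626), at -2.16 against -4.57, a difference of 2.40 (SE 0.363, q 2.09e-07). The lower genes were the U3 small nucleolar RNA genes SNORD3A, at -6.86 against -5.52 with q 0.00127, SNORD3B-2, at -11.48 against -4.28 with q 0.00127, and SNORD3C, at -7.90 against -3.14 with q 1.33e-14. The last was RP11-328L11.1, at -0.57 against 0.24 with q 5.98e-07. These 4 lower genes were picked after their values were seen. The U3 genes are near-identical copies, and SNORD3B-2 stood at 1956 FPKM in ΔΔG3BP1/2 totals and 19.5 FPKM in parental totals. At an unadjusted threshold of 0.05 the test found 57 genes, or 0.459%, where about 5% would pass with errors of the right size and no change, and the robust SD of its z values was 0.481. The errors are thus too large for this pair and the 5 genes are a cautious count. With the deposited statistic taken as it stands 1 gene, SNORD3C, passed. By size alone, 75 genes lay at least 2-fold higher and 66 lower, against 24 and 42 with the planned pseudocount of 1 and 27 and 43 at FPKM of at least 5, so the balance turned. RPL7 was among the 75, at -0.09 against -2.49, and AP000275.65 among the 66, at 0.84 against 2.50. The value of RPL7 in the ΔΔG3BP1/2 cells turns positive with equal upper quartiles.

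As groups, several lists had slightly higher ratios of cores over total in the ΔΔG3BP1/2 cells. Ribosomal protein mRNAs had a median difference of 0.35, with 68 of 71 above 0, and lists of like abundance drawn at random had medians between 0.02 and 0.15. Giant-protein mRNAs had a median difference of 0.20, with 38 of 45 above 0, histone mRNAs of 0.27 and oxidative phosphorylation mRNAs of 0.19. Each of these lay outside the range of random lists, as did mitochondrial RNAs at 0.25, secreted protein mRNAs at 0.11, ZNF genes at 0.06 and, on the lower side, small structured RNAs at -0.52. In totals, giant-protein, histone, mitochondrial and secreted protein mRNAs were lower in the ΔΔG3BP1/2 cells, by medians of -0.41, -0.31, -0.49 and -0.40, and small structured RNAs were higher, by 0.79, so the ratios need not mean more or less RNA in cores. Totals of ribosomal protein and oxidative phosphorylation mRNAs differed by medians of -0.12 and -0.12, near the -0.10 of all genes. Of the ribosomal, giant-protein, histone and oxidative phosphorylation lists, RPS27 was the only member to pass the test gene by gene. Genes for the granule's own proteins had a median difference of 0.02 and chromatin regulators of 0.03, both inside that range.

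**Figure D1:**
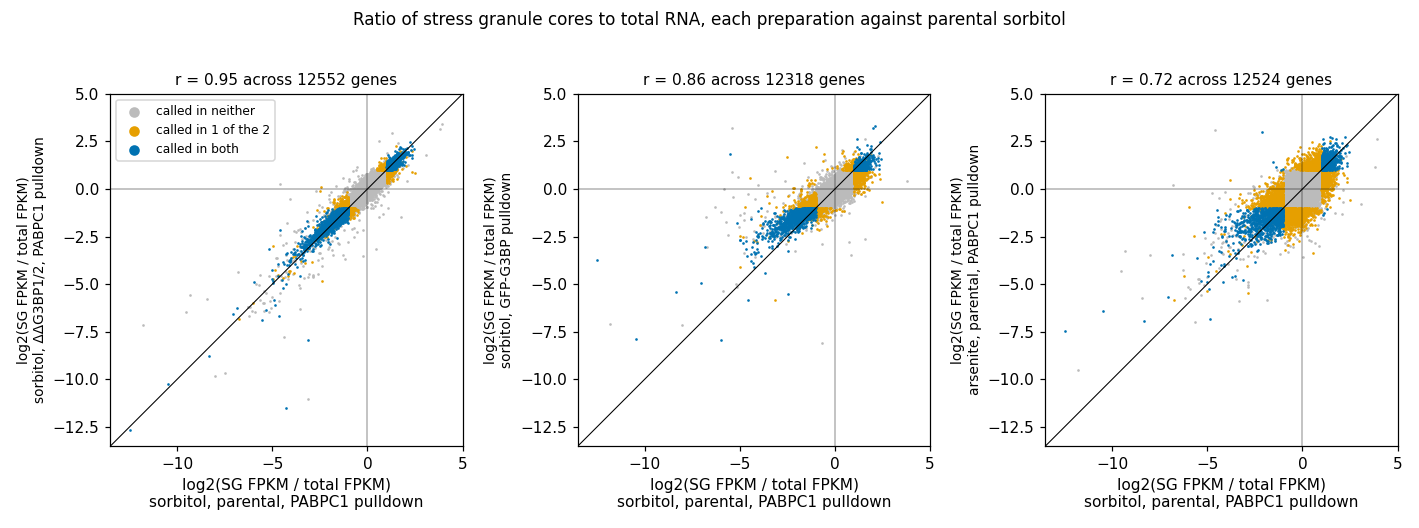
Log2 ratio of core FPKM over total FPKM for each gene in ΔΔG3BP1/2 sorbitol, GFP-G3BP sorbitol and parental arsenite cores (vertical axes), against parental sorbitol cores (horizontal axes), with the line of equality and colours for genes called in both, in either direction, in 1 or in neither. Points lie closest to the line for the ΔΔG3BP1/2 cells (r 0.951), less so for the GFP pulldown (r 0.860) and least for arsenite (r 0.715).

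The fourth comparison asks which RNAs come down through GFP-tagged G3BP after sorbitol, so both the bait and the cell line differ from the PABPC1 preparations. MT-ND6 at 2.32, GNAO1 at 2.48 and NORAD at 1.44 were enriched, each with a q of 0.000273 in the authors' deposited table. RPPH1 at -7.86 and RPS27 at -5.82 were depleted with the same q. PABPC1 mRNA had a log2 ratio of -0.02 here, which turns positive when ratios are centred on their median or scaled to equal upper quartiles. In the PABPC1 pulldowns it was enriched only in parental sorbitol cores, at 1.23. It stood at 0.82 in ΔΔG3BP1/2 sorbitol and 0.18 in parental arsenite cores. AHNAK was listed at 0 in the GFP-G3BP cores and at 168 FPKM in their total, so no ratio can be given. It stood at 2.63, 1.10 and 1.77 in the PABPC1 preparations. Whether the 0 is a measured absence or a missing value cannot be told here.

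In GFP-G3BP cores 577 genes were called enriched and 1258 depleted of 12383 with a value, by the q values of the authors' deposited table. With upper quartiles made equal the counts were 826 and 986. Chromatin regulators were enriched in 25 of 44 cases with a median of 1.10, KMT2D at 1.63 among them, and giant-protein mRNAs in 5, with a median of 0.52 and with MYH9 at -0.09, a value that turns positive with equal upper quartiles. Ribosomal protein mRNAs were depleted in 64 of 71 cases, histone mRNAs in 32 of 36 and oxidative phosphorylation mRNAs in 36 of 69. Examples are RPL37A at -1.68, HIST1H1C at -2.35 and NDUFB9 at -2.12. The strongest genes not yet named were RP11-598P20.3, RP11-50B3.1 and CTD-2124B8.2 at 3.32, 3.19 and 2.63, and RNU12, RN7SL3 and RN7SKP203 at -5.50, -5.43 and -4.95.

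Against the parental PABPC1 pulldown after sorbitol, the GFP pulldown gave flatter ratios, with r of 0.860, rho of 0.872 and a slope of 0.740 across 12318 genes. Of 990 genes enriched in the PABPC1 pulldown 405 were enriched in both, against 46.1 if independent, and of 1701 depleted genes 1058 were shared, against 173. SNORD3A was the 1 gene called in opposite directions, at 1.82 against -5.52, with totals of 464 and 28506 FPKM. The difference test found 557 of 12220 genes, 332 higher and 225 lower through GFP, and 180 of the 557 were also at least 2-fold apart. Among ribosomal protein mRNAs 27 were higher and 2 lower (38 and 3 adjusted over the list alone), and among oxidative phosphorylation mRNAs 16 were higher and none lower (26 and 1 adjusted over the list alone). RMRP was higher through GFP, at -3.04 against -6.84. RPL7 was higher as well, at 1.67 against -2.49 with q 0.000263. Chromatin regulators had a median difference of -0.37, with 1 higher and 4 lower, and PABPC1 was lower by the test, with a difference of -1.25 and q 4.32e-05. SF3A1, a splicing factor gene, stood at -0.15 against 1.52 with q 0.0136, and the ubiquitin ligase gene CBLB at -0.29 against 1.35 with q 0.0031. With the deposited statistic taken as it stands, 30 genes passed, 27 higher and 3 lower, and PABPC1, RPL7, SF3A1 and CBLB did not. In that form 5 ribosomal protein mRNAs were higher and none lower, and no oxidative phosphorylation mRNA or chromatin regulator passed. With PABPC1 cores of the ΔΔG3BP1/2 cells in place of the parental ones, the test found 58 of 12189 genes, 45 higher and 13 lower through GFP. The errors of the ΔΔG3BP1/2 comparison are larger. In those cores CBLB stood at 0.43 and PABPC1 at 0.82. The antibody and the cell line changed together, so their parts cannot be told apart. Flatter ratios alone would place depleted lists higher and enriched lists lower through GFP. The list differences were not tested against that, so they do not show a choice of particular RNAs.

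Arsenite and sorbitol cores of parental cells correlated less with each other than the sorbitol cores did among themselves. Stress and preparation changed together here, so a difference cannot be credited to the stress alone. RNAs made in mitochondria and mRNAs of giant and secreted proteins stood higher over total in arsenite cores, and the mRNAs of β-actin, of PABPC1 and of part of the other granule proteins stood higher over total in sorbitol cores. GAS5, a small nucleolar RNA host (chromosome 1, 173832386 to 173872687), was at 0.45 after arsenite and -3.78 after sorbitol, a difference of 4.23 with q 7.86e-13. ACTB, which encodes β-actin, was depleted at -1.12 after arsenite and stood at 0.63 after sorbitol, a difference of -1.75 with q 7.97e-13. In the stricter form of the test q was 3.57e-05 for GAS5 and 0.00017 for ACTB. AGRN, which encodes the matrix protein agrin, was enriched at 1.41 after arsenite and depleted at -1.54 after sorbitol, and it was picked after its values were seen.

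The log2 ratios of both stresses correlated with r of 0.715 and rho of 0.687 across 12524 genes. Both called 486 genes enriched, against 93.8 if independent, and 869 depleted, against 241, and 8 genes were called in opposite directions. The difference test found 3089 of 12409 genes, 1439 higher and 1650 lower in arsenite cores. Of these, 1483 were also at least 2-fold apart. Of the mitochondrial RNAs 13 of 15 were higher in arsenite and none lower (13 and 1 adjusted over the list alone), with a median difference of 1.66. MT-RNR1, the small ribosomal RNA of mitochondria, went from -3.30 to -0.25. Giant-protein mRNAs had a median difference of 0.80, with 18 of 45 higher, 22 adjusted over the list alone, and none lower. AHNAK and DYNC1H1 differed by 1.54 and 1.43, with q of 0.000486 and 0.000557. Secreted and matrix protein mRNAs had a median difference of 0.61, with 18 of 37 higher and 4 lower (20 and 4 adjusted over the list alone). Genes for granule proteins went the other way, with a median difference of -0.62 and with 2 of 38 higher and 15 lower (2 and 18 adjusted over the list alone), while their totals were higher in arsenite by a median of 0.35. PABPC1 differed by -1.05 with q 4.65e-05, with 707 and 683 FPKM in cores and 623 and 290 FPKM in totals, and G3BP2 by -0.78 with q 0.0286. Chromatin regulators had a median difference of 0.01, inside the range of random lists, with 3 members higher and 3 lower, and none in either direction adjusted over the list alone or in the stricter form of the test. RMRP was higher in arsenite, at -3.48 against -6.84, and the splicing regulator HNRNPH3 lower, at -1.39 against 1.06 with q 2.78e-09. With the deposited statistic taken as it stands, 755 genes passed, 349 higher and 406 lower, while AHNAK and DYNC1H1, both at q 0.128, PABPC1 at q 0.0519 and G3BP2 at q 0.396 missed the threshold. In that form 11 mitochondrial RNAs and 6 giant-protein mRNAs were higher and none lower, 7 secreted protein mRNAs were higher and none lower, and 5 granule protein mRNAs were lower and none higher. By size alone, 1034 genes lay at least 2-fold higher and 1024 lower, or 1261 and 809 once the ratios were centred on their median and 710 and 770 with a pseudocount of 1, so neither direction prevails.

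**Figure D2:**
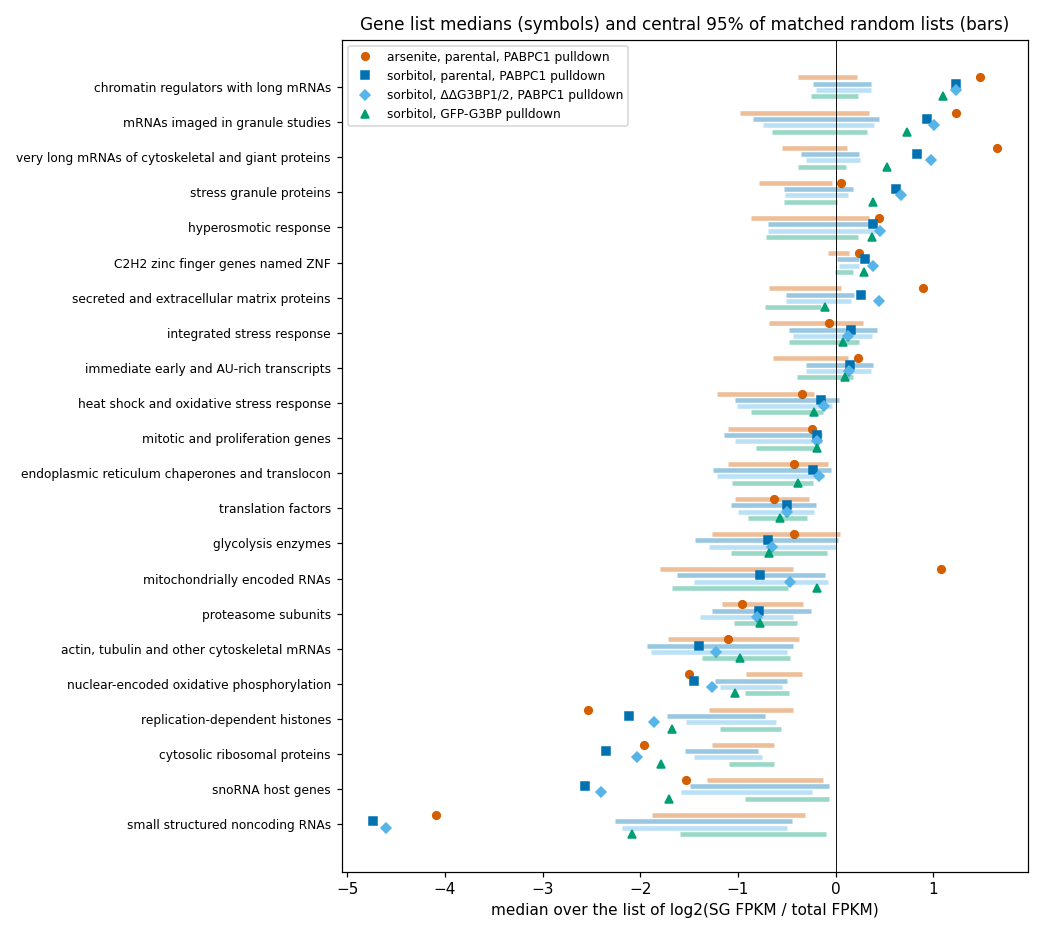
Median log2 ratio of core FPKM over total FPKM for each gene list with at least 10 measured members (symbols, 1 per preparation) and the central 95% of medians of 10000 random lists matched on expression (bars). Giant-protein mRNAs lie highest after arsenite (1.65) and chromatin regulators lie above 1 in all 4 preparations, while histone, ribosomal protein and small structured RNAs lie below their bars.

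Across all 4 preparations, 231 genes were enriched and 530 depleted throughout, against 0.311 and 2.70 expected if the calls were independent. The imprinted zinc finger gene PEG3 was enriched at 1.89, 1.96, 2.11 and 1.73, and NORAD at 1.85, 1.29, 1.55 and 1.44. The amino acid transporter gene SLC7A5 was enriched at 1.23, 1.27, 1.08 and 1.06. The translation elongation factor gene EEF1A1 was depleted at -1.39, -2.32, -2.33 and -1.74, and TMSB10, a thymosin that binds actin, at -2.21, -2.84, -2.75 and -2.03. PEG3 and SLC7A5 were picked after their values were seen. Among the 6 pairings of preparations, the 3 sorbitol ones correlated between 0.849 and 0.951, and the 3 that set arsenite against sorbitol between 0.686 and 0.715. TFRC, the transferrin receptor gene, was called in none of them, at 0.45, 0.06, 0.16 and 0.14.

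Total RNA itself differed between the groups, though the separate normalisation leaves these as descriptions without a test, and the medians of all genes were shifted by -0.10 and -0.13. After sorbitol, the cells labelled ΔΔG3BP1/2 held more mRNA of the apoptosis inhibitor BIRC3, 31.6 against 1.53 FPKM, and of the cytokine IL32, 32.5 against 1.95 FPKM, than parental cells. The stress-induced NUPR1 stood at 53.8 against 15.9 FPKM and the metallothionein MT2A at 154 against 64.5 FPKM. TNFRSF11B, the decoy receptor osteoprotegerin, stood at 3.31 against 12.4 FPKM and the guidance factor SEMA3A at 8.67 against 30.6 FPKM. In all, 231 genes were at least 2-fold higher and 202 lower, or 287 and 145 after centring, and log2 totals correlated with r of 0.975. RNU5D-1 and RNU5E-6P stood at 25.3 and 21.2 times the parental level.

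Arsenite totals of parental cells held more immediate early mRNA than sorbitol totals. FOS stood at 93.1 against 6.23 FPKM, EGR1 at 69.7 against 5.31 FPKM, and the heme oxygenase gene HMOX1 at 52.6 against 12.3 FPKM. PPP1R15A, a phosphatase subunit of the integrated stress response, stood at 63.4 against 8.70 FPKM, and DDIT3 at 33.3 against 9.37 FPKM. NFAT5, the main transcription factor of osmotic stress, was also higher in the arsenite totals, at 29.6 against 13.0 FPKM. Of 32 immediate early genes 17 were at least 2-fold higher and none lower, of 24 heat shock and oxidative stress genes 7 were higher and none lower, and of 15 mitochondrial RNAs 12 were higher. Of 36 histone mRNAs 26 were at least 2-fold lower, with HIST1H2AE at 3.90 against 201 FPKM, and of 69 oxidative phosphorylation mRNAs 42. RGS4, a regulator of G-protein signalling, was among the genes highest in arsenite over sorbitol totals, at 68.6 against 2.38 FPKM. TGFBI was among the lowest at 63.9 against 809 FPKM. The series holds no unstressed parental sample, so it cannot be told which stress, if either, moved a level. Overall counts were 858 higher and 1159 lower by at least 2-fold, or 1105 and 833 after centring and 1168 and 786 with equal upper quartiles.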

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

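All tests in this part were chosen after the results were seen. A test of the difference between preparations picked out 5 genes between cells labelled ΔΔG3BP1/2 and parental cells after sorbitol, 557 between the GFP and PABPC1 pulldowns after sorbitol, and 3089 between arsenite and sorbitol in parental cells. These counts have no minimum fold, and those also at least 2-fold apart numbered 4, 180 and 1483.

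The authors' deposited table classes fewer genes in the parental sorbitol comparison than that comparison's own q values give. Its flag matched its own q in 66.3% of genes, and 632 genes past both thresholds, 227 enriched and 405 depleted, are listed as neither. The flag equals the arsenite flag in 100% of genes, which is consistent with a column carried over from the arsenite comparison. Another q threshold is argued against, since the best single cutoff on the sorbitol q values misplaced 33.4% of genes. No biological explanation was tested, and counts from each comparison's own q were used for the report.

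Cores of the cells labelled ΔΔG3BP1/2 had 2264 calls and parental sorbitol cores 2714. When the ΔΔG3BP1/2 ratios were given the parental error, the calls rose from 2373 with their own error to 2672, near the 2789 of parental ratios recomputed in the same way, so a larger error in that comparison may account for most of the gap. Much weaker sorting across all genes is argued against, because the slope of the log2 ratios was 0.975. The slope assumes equal error in both preparations, and a larger error in the ΔΔG3BP1/2 comparison would raise it. Slightly weaker sorting therefore stays open. Why the error is larger stays open, as does a biological difference in single genes, since only 57 genes, or 0.459%, passed the unadjusted threshold of 0.05 in the difference test, fewer than errors of the right size would give.

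RNAs made in mitochondria and mRNAs of secreted proteins stood higher over total in arsenite than in sorbitol cores, by medians of 1.66 and 0.61. Whole mitochondria carried along as the only difference would raise the fold of every mitochondrial RNA by 1 common amount, and 4 of 15 lay beyond 2 standard errors of the common rise of 0.809, with rises from -0.78 for MT-ND6 to 2.60 for MT-ND5. Endoplasmic reticulum carried along as the only difference is argued against for the secreted part, since mRNAs of its chaperones and translocon had a median difference of -0.17 and an upper quartile of 0.12. A mix of carried mitochondria or endoplasmic reticulum and another change may still hold, and so may a response to the stress itself. The stresses also differ in dose, in 1 against 2.5 hours and in the preparation of the samples, and none of these was tested apart.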

How the results depend on the processing

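The difference test, the use of a pseudocount of 1 as an alternative instead of the planned main choice, and that of the deposited classes were decided after the data were seen, and the other alternatives before. Of 198 alternatives to the main counts and correlations, 155 stayed within their tolerance, and 43 moved. The balance of higher and lower genes turned in several. With equal upper quartiles enriched genes outnumbered depleted ones in arsenite (1536 and 1437) and ΔΔG3BP1/2 cores (1233 and 1171). Arsenite against sorbitol totals turned when centred (1105 and 833) or with equal upper quartiles (1168 and 786), and ΔΔG3BP1/2 against parental totals without mitochondrial and small RNAs (174 and 196). Arsenite against sorbitol cores, near balance, turned with a pseudocount of 1 (710 and 770), at FPKM of at least 5 (710 and 824), without mitochondrial and small RNAs (976 and 1004) and in both forms of the test. A pseudocount of 5 left 546 enriched and 969 depleted genes in arsenite, 318 and 1093 in parental sorbitol, 289 enriched in ΔΔG3BP1/2 cells, and 155 and 789 in GFP-G3BP cores, since it shrinks ratios of genes with low FPKM. With no minimum fold, a looser criterion by construction, the counts were 3100 and 3637, 2953 and 2971, 1714 enriched, and 2663 and 3355. Genes at least 2-fold higher in ΔΔG3BP1/2 than parental cores numbered 24 with a pseudocount of 1, 9 with 5 and 27 at FPKM of at least 5, and by the difference test 1, or 0 with the statistic as deposited. Lower genes numbered 42, 31 and 43, so the balance of 75 and 66 turned, then 32 without mitochondrial and small RNAs, 4 by the test and 1 in its stricter form. For the GFP against the PABPC1 pulldown, pseudocounts of 1 and 5 gave 201 and 129 higher and 94 and 41 lower genes, FPKM of at least 5 gave 101 lower, and the stricter test 27 and 3. For arsenite against sorbitol, a pseudocount of 5 gave 411 higher and 386 lower, the test 1650 lower, and its stricter form 349 and 406. All counts by the test have no minimum fold, so their distance from the 2-fold counts partly reflects a changed criterion. In totals, a pseudocount of 5 gave 103 higher and 36 lower for ΔΔG3BP1/2 against parental cells, a pseudocount of 1 gave 102 lower, and for arsenite against sorbitol a pseudocount of 5 gave 313 and 515. The correlation of arsenite with ΔΔG3BP1/2 cores rose to 0.765 at FPKM of at least 10, and the cause was not tested. Between ΔΔG3BP1/2 and parental sorbitol cores the correlation ranged from 0.919 to 0.966 over all settings, and between arsenite and sorbitol in parental cells from 0.687 to 0.763. List medians kept their value in 294 of 300 alternatives. At FPKM of at least 5, which leaves fewer genes, the small structured RNAs moved to -4.56 in arsenite, -5.03 in ΔΔG3BP1/2 and -1.13 in GFP-G3BP cores, and markers of other cell types to -1.05 in parental sorbitol, -1.01 in ΔΔG3BP1/2 and -0.96 in GFP-G3BP cores. Shares of calls common to a pair of preparations moved in 11 of 12 cases when the minimum fold was lowered to 0.58 on the log2 scale. The shares fell for ΔΔG3BP1/2 against parental sorbitol and rose for the other pairs. Over these lists, the 12 shares and all single named genes, 3540 alternatives kept the call or stayed within tolerance, 51 moved, 99 ended a call and 17 gave one. No paired analysis was possible because the table holds 1 value per group. For the same reason leaving out each replicate, fits on chosen groups, count models and list tests with an estimated correlation were not run. Comparisons with unstressed cells and the transcript length alternatives were not run, and a setting without the FPKM minimum changed nothing, since the lowest total FPKM is 1.00. Depth is unknown, and genes of low FPKM are where a pseudocount moves the ratios most.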

Other observations

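The classes by symbol and the relation to locus span were chosen after the data were seen. Vault RNAs, copies of the 7SL and 7SK RNAs, spliceosomal RNAs, small Cajal body RNAs and small nucleolar RNAs, grouped by symbol, had no enriched member in any of the 3 PABPC1 preparations. SNORD3A was enriched in the GFP-G3BP cores. Spliceosomal RNAs and their copies were depleted in 11, 8 and 10 of 24 cases in the PABPC1 preparations, with medians of -4.35, -4.27 and -4.52, and in 3 of 16 cases with a median of -0.41 in the GFP-G3BP cores, while 5, 6, 0 and 5 were at 0 in cores. H/ACA small nucleolar RNAs had median log2 ratios of -3.51, -3.48, -4.58 and -2.11, in the order parental arsenite, parental sorbitol, ΔΔG3BP1/2 sorbitol and GFP-G3BP sorbitol, with 5, 5, 5 and 1 of them called depleted. Of the 93, 93, 93 and 47 measured, 43, 32, 30 and 27 were at 0 in cores, which can be neither called nor counted in a median. Pseudogenes of ribosomal proteins went with their parent genes, with 56, 58, 48 and 48 depleted and medians of -1.89, -2.12, -1.84 and -1.47. Whether such copies share reads with the parent mRNAs was not tested. Ratios rose with the genomic span of the locus, with Spearman's rho across genes of 0.333, 0.373, 0.363 and 0.350 among genes with a locus of their own. With the genes parted into low, middle and high total FPKM, equal in number, rho in arsenite was 0.252, 0.301 and 0.458. Genes are not independent replicates, and locus span includes introns.

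Other gene lists were less uniform. Zinc finger genes named ZNF were enriched in 41, 34, 41 and 35 of 336 cases (333 in the GFP-G3BP comparison) and depleted in 3, 9, 8 and 5, with medians of 0.24, 0.30, 0.38 and 0.29 that lay above random lists, while ZNF207 and ZNF410 stood at -0.89 and -0.32 in arsenite. Proteasome mRNAs were depleted in 14, 14, 11 and 10 of 32 cases, with list medians inside the range of random lists, PSMB3 at -2.06, -3.77, -3.63 and -2.52 and PSMA7 at -1.38, -1.60, -1.64 and -1.12. Actin, tubulin and other cytoskeletal mRNAs, such as those of cofilin and myosin light chains, were depleted in 9, 10, 10 and 8 of 17 cases, with medians of -1.11, -1.40, -1.22 and -0.98 inside the range of random lists. Translation factors were enriched in 1, 3, 2 and 0 and depleted in 12, 16, 14 and 13 of 43 cases, with medians inside that range and EEF1D at -0.57, -1.83, -1.71 and -1.65. Glycolysis mRNAs were depleted in 1, 4, 4 and 1 of 14 cases, with medians inside that range and ENO1 at -0.83, -1.37, -1.40 and -0.86. LDHA stood at -0.68, 0.17, 0.39 and -0.08, and the last value turns positive with equal upper quartiles. The mRNAs followed in granule imaging studies, 3 of 10 of them cyclins or kinases, had medians of 1.23, 0.94, 1.01 and 0.73, above random lists, and CTNNB1 stood at 0.52, -0.04, -0.09 and 0.26.

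Heat shock and oxidative stress mRNAs were enriched in 0, 1, 1 and 1 and depleted in 6, 3, 2 and 3 of 24 cases, with medians of -0.35, -0.15, -0.13 and -0.22, of which the ΔΔG3BP1/2 value turns positive with equal upper quartiles. HSPA8, a constitutive chaperone, stood at -0.21, -0.65, -0.71 and -0.71, and BAG3 was enriched after sorbitol at 1.31 in parental and 1.18 in ΔΔG3BP1/2 cells. BAG3 was picked after its values were seen. Immediate early mRNAs were enriched in 3, 5, 4 and 2 and depleted in 0, 3, 4 and 2 of 32 cases, with ID1 at 0.25, -0.96, -0.96 and -0.60 and MCL1 at 0.36, 0.43, 0.56 and 0.37. The medians of this list were 0.23, 0.14, 0.13 and 0.09, above random lists in arsenite and inside their range in the sorbitol preparations. Integrated stress response mRNAs were enriched in 2, 1, 2 and 2 and depleted in 1, 2, 3 and 0 of 21 cases, with medians of -0.07, 0.15, 0.13 and 0.07, the first turning positive when centred or scaled to equal upper quartiles. ATF4 stood at -0.77, -0.19, -0.14 and -0.27 and SLC3A2 at -0.48, -1.36, -1.41 and -0.97. Hyperosmotic response mRNAs were enriched in 1, 1, 1 and 2 and depleted in 1, 3, 3 and 2 of 13 cases, with medians of 0.44, 0.38, 0.46 and 0.38 that lay above random lists except in parental sorbitol, and NFAT5 was enriched in the 3 sorbitol preparations at 1.61, 1.23 and 1.72. SLC38A2 stood at 0.10, 0.38, 0.70 and 0.77. Endoplasmic reticulum chaperone and translocon mRNAs were depleted in 2, 5, 2 and 2 of 21 cases, with CALR at -0.75, -0.32, -0.56 and -0.67 and CANX at 0.13, 0.91, 0.94 and 0.72. The medians of the heat shock, integrated stress response, endoplasmic reticulum and mitotic lists lay inside the range of random lists in all 4 preparations. Secreted protein mRNAs had a median of -0.11 in GFP-G3BP cores, which turns positive with equal upper quartiles.

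Mitotic and proliferation genes had 1, 3, 3 and 1 enriched and 3, 0, 0 and 0 depleted of 28, with CCNB1 at -0.52, -0.83, -0.70 and -0.42 and TYMS at -0.73, -0.04, -0.02 and -0.02, of which the last 3 turn positive with equal upper quartiles. With that scaling the sorbitol value of CTNNB1 in parental cells turns positive too, as do those of CTNNB1, ATF4 and SNHG16 in ΔΔG3BP1/2 cells. Nuclear long noncoding RNAs had 0, 1, 1 and 1 enriched and 2, 3, 2 and 2 depleted of 6, with MALAT1 at -2.08, -1.40, -1.10 and -0.65 and PVT1 at -0.86, -2.21, -2.15 and -1.19. Noncoding RNAs reported in RNA granules had 1 enriched member of 6 in every preparation, NORAD, and 2, 1, 1 and 1 depleted, with LINC00152 at -1.48, -2.18, -2.14 and -2.22 and SNHG16 at -0.68, -0.13, -0.03 and 0.15. Hosts of small nucleolar RNAs were depleted in 13, 10 and 13 of 16 cases in the 3 sorbitol preparations, with SNHG7 between -5.01 and -3.99 in all 4. The small structured RNAs had 7, 8, 9 and 4 depleted members of 14, 14, 14 and 10, with 4, 2, 1 and 4 more at 0 in cores. Of 25 markers of other cell types, 4 were in the table, and of these KRT8 and KRT18, which epithelial cells hold in quantity, stood at 53.3 and 97.2 FPKM in arsenite totals. KRT8, KRT18, EPCAM and SNAP25 had median ratios of -0.75, -0.43, -0.35 and -0.49, inside the range of random lists.

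Further lists differed between preparations by more than random lists did. Through GFP against PABPC1 after sorbitol, median differences were 3.03 for small structured RNAs, with 5 of 6 higher by the test, and 0.63 for small nucleolar RNA hosts, with 3 of 16 higher. They were -0.32 for secreted protein mRNAs, -0.21 for giant-protein mRNAs and -0.18 for mRNAs of granule proteins, with 2, 0 and 3 members lower by the test. Of the 10 small structured RNAs measured in the GFP-G3BP comparison, 4 had a core value of 0 and thus no ratio or difference. List totals were not compared for this pair, so a higher ratio need not mean more of these RNAs in GFP cores. Random lists were matched on expression and not on the ratio, so they do not account for the flatter ratios through GFP. In arsenite against sorbitol, ribosomal protein mRNAs had a median difference of 0.44, with 29 of 71 higher and 7 lower, while their totals were lower in arsenite by a median of -0.92. For small nucleolar RNA hosts the median difference was 0.62, with 3 higher and 2 lower, and for small structured RNAs 1.44, with 4 of 10 higher and 1 lower. Hyperosmotic response mRNAs had a median difference of 0.53, with 5 of 13 higher and none lower, and heat shock and oxidative stress mRNAs of -0.42, with 2 of 24 higher and 8 lower. In totals of arsenite against sorbitol the last 4 lists differed by medians of -0.41, -0.53, 0.34 and 0.42. With the deposited statistic taken as it stands, GFP against PABPC1 kept 4 higher small structured RNAs, 1 higher small nucleolar RNA host and no lower secreted, giant or granule protein mRNA. Arsenite against sorbitol then kept 15 ribosomal protein mRNAs higher and none lower, 2 hosts higher and 1 lower, and 4 small structured RNAs higher and none lower. It kept 1 hyperosmotic mRNA higher and 1 heat shock or oxidative stress mRNA lower.

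The 11 mitochondrial RNAs with values in all comparisons made up 2.27% of the FPKM sum in arsenite cores and 0.657% in arsenite totals. In parental sorbitol these shares were 0.247% and 0.152%, in ΔΔG3BP1/2 sorbitol 0.226% and 0.0995%, and in GFP-G3BP sorbitol 3.69% and 2.27%. In FPKM itself, these RNAs summed to less in cores than in totals in all sorbitol preparations. The sums were 1081 against 1674 in parental, 978 against 1275 in ΔΔG3BP1/2 and 23609.5 against 25240 in GFP-G3BP sorbitol. The sums of whole columns were also lower in cores, so a higher share does not mean a higher ratio of cores over total. The 4 comparisons were normalised separately, so these shares describe each column alone.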
